A study of Arabidopsis thaliana with 4 samples.

How the data were processed

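RNA was measured in aerial organs of soil-grown Arabidopsis thaliana at Boyes stage 1.09, in 2 libraries of the otp90 knock-out line SM_3_29659 and 2 libraries of the wild type Col-0. Per the labels' protocols, plants grew at 18 to 21 °C with light of up to 90 µE per square metre and second and no treatment, total RNA was extracted with Trizol, and rRNA-depleted, stranded, single-end Ion Proton libraries were sized at 230 bp. The labels do not say whether the 2 libraries of a genotype came from separate plants, so p-values measure the spread between these libraries, which may be technical.

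The deposited values are raw read counts per gene model, which the authors made with sam2pkm, per the file headers. Per the file headers, reads whose best and second alignment scores tied were removed before counting. The genome build was TAIR10, per the submitters' processing notes, and the aligner is not given in the sources used here. The headers also give the reads parsed, mapped, removed and counted, and the length of each gene model. The removal took 87.0% and 80.4% of the mapped reads in the otp90 libraries and 79.9% and 84.8% in the Col-0 libraries, so genes with a near-identical copy (the plastid inverted repeat, mitochondrial genes copied in the nucleus, LHCB1, RBCS and the ATP synthase beta genes) were undercounted, and their values are uncertain. Whether the counting used strand is not given in the sources used here, so reads of overlapping and antisense genes may be shared.

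Gene names, products and gene types came from the TAIR10.1 annotation by locus tag, which matched 32835 of 33602 gene models. The build differs from that of the files, so no coordinates are given. The annotation does not pair the mitochondrial and plastid locus tags with symbols. Those symbols came from lists written before the data were examined and were compared by length with the annotated genes of the same symbol. In mitochondria 22 lengths were equal, 1 lay within 2%, 6 differed (nad1, cox3, atp9, ccmFC, mttB and matR) and 9 had no gene of that symbol. In plastids 71 were equal, 1 lay within 2% and 2 differed, both copies of ndhB. No locus is named OTP90 in that annotation, so the level of the targeted gene was not analysed here.

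Counts were analysed with edgeR 4.0.16 in R 4.3.3. The 15 rRNA gene models were left out of library sizes and tests because the kit depletes rRNA. Genes were kept by filterByExpr, which left 11938, libraries were scaled by TMM, and genotypes were compared with the two-sided quasi-likelihood test without a replicate block. P-values were adjusted by Benjamini-Hochberg and called at 0.05. CPM values are TMM-scaled counts relative to library size. The standard error of a log2 fold change was taken from the size of the fold change and the F statistic. Before the data were examined, the design, 26 gene lists, the alternatives and the rule for named genes were fixed. The rule names OTP90 if it is annotated, the largest changes among called genes, up to 4 members with the smallest p of each list, and, where fewer than 10 genes are called, the 10 with the smallest p as values and not as calls. The text uses the last of these and the 2 members with the smallest p of each list. Outside the rule, LHCB1.1 and ASN1 as examples of calls with opposite signs, MIR398c and CSD2 with a copper list, the genes at 0 counts in otp90, and the genes of the comparison of replicate numbers were chosen after their values were seen.

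The lists cover mitochondrial genes for complex I, complexes III and IV, ATP synthase, cytochrome c maturation and ribosomal proteins, and plastid genes for the photosystems, NDH complex, ATP synthase, ribosomal proteins and those read by the nuclear-encoded polymerase. Nuclear lists cover mitochondrial dysfunction, the respiratory chain, mitochondrial chaperones and proteases, organelle RNA factors, photosynthesis, heat shock, salicylic acid, jasmonate, flavonoids, the circadian clock, sugar starvation, senescence, the cell cycle and markers of flowers, roots and seeds. The 21 lists with at least 3 genes tested were compared with the other genes by camera in limma 3.58.1, with a preset correlation of 0.01 and again with an estimated one, on log2 CPM with a prior count of 2. Shares of counts were compared by an exact two-sided permutation test, which with 2 against 2 libraries cannot go below p = 0.333.

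Both tests were tested on simulated data. Counts were drawn 10 times for the 11938 genes of this comparison from the measured means, library sizes and dispersions, with 200 genes changed. The test called 0.4% of 2-fold, 10.0% of 4-fold, 49.2% of 8-fold and 74.0% of 16-fold changes, with 52 false calls over the 10 draws. Camera at an unadjusted p under 0.05, with the preset correlation, found a list of 30 genes shifted 2-fold in 10 of 10 draws and an unshifted list in 0 of 10. Genes varied independently in these draws, and replicate numbers did not differ in them. The measured libraries differed by replicate number, so the rates for genes may not carry over to these data. The lists tested here had as few as 3 genes and estimated correlations of up to 0.981, so the camera rates do not carry over to them.

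Counted reads ranged from 1489112 to 2685718 per library. The biological coefficient of variation was 0.448, and the 95% interval of a log2 fold change had a median width of 1.77 to each side under 20 counts and 1.10 over 200. Alternatives were other scalings (DESeq2 size factors, upper quartile, nuclear genes alone), rRNA genes kept, no low-count filter or 1 CPM in 2 libraries, DESeq2 1.42.0, the edgeR likelihood ratio test, limma voom, a replicate block, a 2-fold threshold and each library left out. The older and the robust quasi-likelihood fits, the restriction to protein-coding nuclear genes, each library left out with rRNA genes kept, and the comparison of replicate numbers with its own alternatives were chosen after seeing the data.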

Results

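The series asked how the aerial transcriptome of otp90, a knock-out named for organelle transcript processing, differs from that of the wild type Col-0. Each genotype had 2 rRNA-depleted RNA libraries. Counted reads were 1489112 and 1841972 in otp90 replicates 1 and 2, and 2685718 and 1828745 in Col-0 replicates 1 and 2. The rRNA genes still took 7.69% and 4.96% of the otp90 counts and 6.78% and 5.77% of the Col-0 counts. Most of this was mitochondrial rrn26, with 6.96% and 3.88% of the otp90 counts and 5.58% and 4.65% of the Col-0 counts. Tied reads had been removed before counting, so these shares do not measure the rRNA left in the libraries. In neither genotype were the replicates 1 library deposited more than once, since their counts differed by a chi-square per degree of freedom of 14.4 in otp90 and 23.7 in Col-0. That comparison does not show that the libraries came from separate plants. The level of the targeted gene was not analysed here, so the labels have no check from that gene.

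No gene passed the test between otp90 and Col-0, and the following genes are those with the smallest p, given as values. AT3G12870, an uncharacterised protein gene, had 39 counts over both otp90 libraries and 3 over both Col-0 libraries, a ratio of 17.5 relative to library totals with a counting interval of 5.57 to 88.7. CRR2 (AT3G46790), a pentatricopeptide repeat protein needed to process plastid ndhB transcripts, was at 24.8 ± 9.19 CPM in otp90 and 5.88 ± 0.18 CPM in Col-0 (SD, n = 2 each), a log2 fold change of 2.07 (SE 0.61). AT1G17350, annotated as NADH:ubiquinone oxidoreductase intermediate-associated protein 30, a name given to assembly factors of respiratory complex I, had 1 count in otp90 and 32 in Col-0, a Col-0 to otp90 ratio of 23.7 with a counting interval of 3.96 to 966. The inositol phosphorylceramide synthase gene AtIPCS2 (AT2G37940), which acts in sphingolipid synthesis, was at 3.63 ± 1.92 CPM in otp90 and 19.3 ± 3.54 CPM in Col-0, a log2 fold change of -2.43 (SE 0.71).

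Of the other 6 genes among the 10 with the smallest p, 5 had positive log2 fold changes. These were the auxin-responsive family gene AT4G12980 (2.35, SE 0.67), the BTB/POZ domain gene AT3G05675 (2.70, SE 0.77), the C1 domain gene AT4G02540 (2.51, SE 0.74), the cytochrome P450 gene CYP705A18 (AT3G20090; 2.66, SE 0.81) and the dirigent-like gene AT3G58090. The last had 23 counts in otp90 and 3 in Col-0, a ratio of 10.3 with a counting interval of 3.12 to 53.8. CIP4 (AT5G37190), which encodes a COP1-interacting protein, had a log2 fold change of -1.95 (SE 0.60). In all 10 genes both otp90 libraries lay on one side of both Col-0 libraries. That separation was found in 25.9% of the 11938 genes tested, where chance gives 33.3%. The libraries differed more by replicate number, described at the end. A share below chance therefore does not show that genotype effects are absent.

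**Figure D1:**
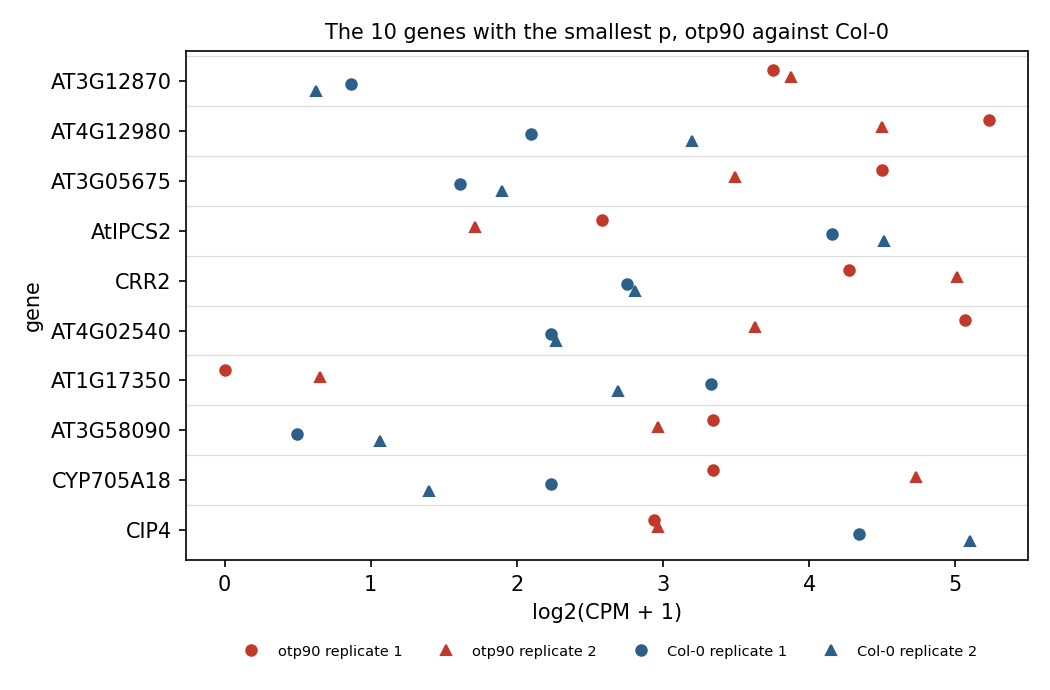
Levels of the 10 genes with the smallest p in each library, as log2(CPM + 1) on the horizontal axis. Each point is 1 library, red for otp90 and blue for Col-0, and the genotypes separate in all 10 genes although none passed the test (adjusted p = 0.9998, edgeR).

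By edgeR's quasi-likelihood test, 0 genes were higher and 0 lower in otp90 at an adjusted p under 0.05, and the smallest adjusted p was 0.9998. At an unadjusted p under 0.05 there were 168 genes, 76 higher and 92 lower, where chance alone gives about 597. This was 1.41% of genes, against 10.7% when the libraries were split by replicate number. The crossed split, with otp90 replicate 1 and Col-0 replicate 2 on one side, gave 4.40%. The genotype fit has no replicate block, so differences between numbers count as spread within genotypes. The shortfall therefore does not show that genotype effects are absent. DESeq2, the edgeR likelihood ratio test and limma voom also called 0 genes, with 96, 242 and 115 at an unadjusted p under 0.05. Leaving out otp90 replicate 1 gave 24 calls, of which 22 were lower, leaving out Col-0 replicate 1 gave 30, all higher, leaving out Col-0 replicate 2 gave 33, of which 26 were higher, and leaving out otp90 replicate 2 gave 0. Without otp90 replicate 1 and without Col-0 replicate 1, 7 genes were called in both, 6 of them in opposite directions, such as LHCB1.1 at -5.71 and 5.62 and ASN1 at -7.14 and 5.42. Of these calls, 21 of 24, 26 of 30 and 6 of 33 were also among the genes that differed between replicate numbers, described at the end.

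Mitochondrial transcripts took 0.46% ± 0.078 of non-rRNA counts in otp90 and 0.442% ± 0.112 in Col-0 (SD, n = 2 each; exact permutation p = 1). In replicate 1 the share was 0.515% in otp90 (95% Wilson interval 0.504 to 0.527, counting error only) and 0.521% in Col-0 (0.512 to 0.530). In replicate 2 it was 0.405% in otp90 (0.395 to 0.414) and 0.362% in Col-0 (0.353 to 0.371). Reads with tied alignments had been removed before counting, so these shares undercount mitochondrial genes that have nuclear copies. With the rRNA genes kept, which count mitochondrial rrn26, the difference was 0.273 percentage points, but the numbers went opposite ways, with 7.90% in otp90 and 6.71% in Col-0 in replicate 1 and 5.18% and 5.82% in replicate 2.

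Among mitochondrial genes, none of the 36 tested of 146 passed the edgeR test, and 0 reached an unadjusted p under 0.05. None passed by DESeq2, the likelihood ratio test or limma voom either. The complex I genes had 4 positive and 5 negative log2 fold changes in 9 tested, with nad1 at 0.47 (SE 0.50) and nad4 at 0.36 (SE 0.54). The genes for complexes III and IV were positive in 3 of 3 tested, with cox3 at 0.45 (SE 0.49) and cox2 at 0.18 (SE 0.47). ATP synthase genes were positive in 4 of 5 tested, with atp9 at 0.25 (SE 0.49) and atp4 at 0.10 (SE 0.48). Both tested genes of cytochrome c maturation and protein transport had positive values, ccmFN2 at 0.33 (SE 0.48) and mttB at 0.47 (SE 0.71). Of 3 ribosomal protein genes tested, rpl2 was at 0.62 (SE 0.55) and rpl16 at -0.23 (SE 0.50), and rpl2 ranged from 0.095 to 1.304 with 1 library left out. The files' models of nad1, cox3, atp9 and mttB differ in length from the annotated genes, and nad4, cox3, cox2, atp9, atp4 and rpl16 changed sign when 1 library was left out.

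Plastid transcripts took 34.7% ± 4.43 of non-rRNA counts in otp90 and 30.5% ± 4.51 in Col-0 (SD, n = 2 each; exact permutation p = 0.667). The share was 37.9% in otp90 and 33.7% in Col-0 in replicate 1, and 31.6% and 27.3% in replicate 2. These values too were taken after tied reads were removed, which undercounts genes of the inverted repeat. The difference of 4.23 percentage points was 1.05 without Col-0 replicate 2, 1.103 without otp90 replicate 1, and over 7 without either other library. Of 133 plastid genes, 95 were tested and 0 passed by edgeR, DESeq2, the likelihood ratio test or limma voom, with 3 at an unadjusted p under 0.05 in edgeR.

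The plastid genes for the NDH complex, which carries cyclic electron flow, had positive log2 fold changes in 10 of 10 tested, with a median of 0.36. Examples were ndhG at 0.48 (SE 0.45) and ndhJ at 0.52 (SE 0.48). Plastid ATP synthase genes were positive in 6 of 6 tested with a median of 0.42, and atpH was at 0.74 (SE 0.52) and atpI at 0.64 (SE 0.49). Neither list passed camera (adjusted p = 0.281 each, and 0.982 with an estimated correlation). The estimate has little to rest on with 4 libraries, so the second value cannot decide. Between libraries of the same replicate number, the NDH median was 0.51 in number 1 and 0.15 in number 2, and the ATP synthase median 0.49 and 0.30. Without otp90 replicate 2 both lists passed camera, with an adjusted p of 0.0362 each.

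The photosystem, cytochrome b6f and rbcL genes of the plastid had a median of 0.21, with 18 of 24 positive, psaI at 0.65 (SE 0.48) and psbI at -0.63 (SE 0.52). With 1 library left out, psaI ranged from 0.19 to 1.05 and psbI from -1.01 to -0.082. Without otp90 replicate 2 this list passed camera (adjusted p = 0.0177). Plastid ribosomal protein genes were positive in 6 of 17 tested with a median of -0.06, with rps16 at -0.54 (SE 0.65) and rpl14 at -0.38 (SE 0.48). The genes read mainly by the nuclear-encoded polymerase had a median of -0.0046, which turned positive (0.014) with DESeq2 size factors and (0.0052) with scaling on nuclear genes, while camera gave the direction as up. Their members with the smallest p were rpoA at -0.33 (SE 0.44) and ycf1 at -0.32 (SE 0.49).

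Among nuclear genes for the respiratory chain, CYC1-1 (AT3G27240), which encodes cytochrome c1 of complex III, was at 11.2 ± 5.35 CPM in otp90 and 32.9 ± 5.25 CPM in Col-0 (SD, n = 2 each). Its log2 fold change was -1.57 (SE 0.56), with an unadjusted p of 0.0211 from edgeR and an adjusted p of 0.9998, so it did not pass. The other 32 tested genes of this list reached no unadjusted p under 0.05, and the list was positive in 14 and negative in 19. The ATP synthase beta gene AT5G08690, one of a set of near-identical copies, was at -0.76 (SE 0.46). AOX1A (AT3G22370), the alternative oxidase that rises when the cytochrome pathway is disturbed, was at 45.9 ± 15.0 CPM in otp90 and 28.4 ± 10.9 CPM in Col-0, a log2 fold change of 0.68 with a 95% interval of -0.49 to 1.84. The mitochondrial dysfunction list was positive in 6 of 9 tested, with the dehydrogenase gene NDB2 at -0.90 (SE 0.75). It passed camera without the low-count filter (adjusted p = 0.0226) and without Col-0 replicate 1, and not otherwise. The second setting leaves Col-0 with number 2 alone, where the list was lower (median log2 fold change between numbers -1.15). Genotype and number cannot be told apart in that fit. Between libraries of the same number, the list median was 0.016 in number 1 and 0.74 in number 2.

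Mitochondrial chaperone and protease genes were positive in 7 of 10, with FTSH4 at 0.39 (SE 0.49) and mtHSC70-2 at 0.31 (SE 0.47). Organelle polymerase, sigma factor and editing cofactor genes were positive in 6 of 16. The plastid editing cofactor gene MORF9 was at 25.2 ± 1.92 CPM in otp90 and 43.4 ± 11.99 CPM in Col-0, a log2 fold change of -0.78 (SE 0.47), and the sigma factor gene SIG3 was at 46.9 ± 2.84 and 27.9 ± 9.90 CPM, a log2 fold change of 0.75 (SE 0.48). Nuclear photosynthesis genes were positive in 13 and negative in 21 of 34, with PSAF at -0.63 (SE 0.60) and GAPB at 0.63 (SE 0.61). That list passed camera as lower without otp90 replicate 1, which leaves otp90 with number 2 alone. It passed as higher without otp90 replicate 2, which leaves otp90 with number 1 alone. The list was also lower in number 2 (median log2 fold change between numbers -0.38), so these fits cannot tell genotype and number apart.

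Stress, hormone and clock genes also gave 0 calls. Jasmonate genes were positive in 7 of 10 tested, with the synthesis genes AOS at 0.58 (SE 0.47) and LOX2 at 0.75 (SE 0.65), and the list median was 0.89 between the number 1 libraries and -0.14 between the number 2 libraries. Salicylic acid genes were negative in 5 of 8, with the defence regulators PAD4 at -1.12 (SE 0.71) and EDS1 at -0.58 (SE 0.52). That list passed camera as lower without otp90 replicate 1 and without Col-0 replicate 2. Both settings weight otp90 towards replicate number 2, where the list was also lower (median log2 fold change between numbers -1.09), so genotype and number cannot be told apart. Circadian genes were negative in 8 of 11 with a median of -0.65, with PRR5 at -1.27 (SE 0.80) and FKF1 at -0.86 (SE 0.65), and the median was -1.31 between the number 1 libraries and 0.19 between the number 2 libraries. Sugar starvation genes were negative in 8 of 10 with a median of -0.70, and -0.58 and -0.63 within numbers 1 and 2. It passed camera as lower without otp90 replicate 1 (adjusted p = 1.34e-05) and without Col-0 replicate 2 (0.00106). In that list MCCB was at -0.68 (SE 0.53) and SEN1 at -2.06 (SE 1.69). SEN1 was called by edgeR as lower without otp90 replicate 1 (adjusted p = 1.1e-05) and without Col-0 replicate 2 (0.0015), and its value was 3.64 without Col-0 replicate 1. Both lists hold genes that differed between replicate numbers.

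Of 3 flavonoid genes tested, F3H was at 0.85 (SE 1.01) and CHS at -0.28 (SE 0.93), with a median of -0.12 while camera gave the direction as up. That list passed camera as higher without otp90 replicate 1 and without Col-0 replicate 2. Both settings weight otp90 towards replicate number 2, where the list was also higher (median log2 fold change between numbers 2.45). Genotype and number cannot be told apart there. Of 5 senescence genes, 1 was positive, with SAG13 at 0.78 (SE 1.13) and WRKY53 at -0.60 (SE 1.23), a median of -0.21 and again an upward direction by camera, which it passed without Col-0 replicate 1 (adjusted p = 0.017). Of 4 cell cycle genes, 2 were positive, with CDKB2;2 at -0.77 (SE 0.79) and KNOLLE at -0.53 (SE 0.66). The heat shock genes HSP101 and HSP90.1 were at 0.11 (SE 0.59) and -0.10 (SE 0.99). Among markers of other tissues, the root gene PYK10 was at 58.2 ± 47.1 CPM in otp90 and 24.4 ± 9.52 CPM in Col-0, a log2 fold change of 1.27 (SE 0.66) that was 0.066 without otp90 replicate 2, and the floral transition gene SOC1 was at 0.65 (SE 0.65). No seed storage gene had enough counts to be tested.

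**Figure D2:**
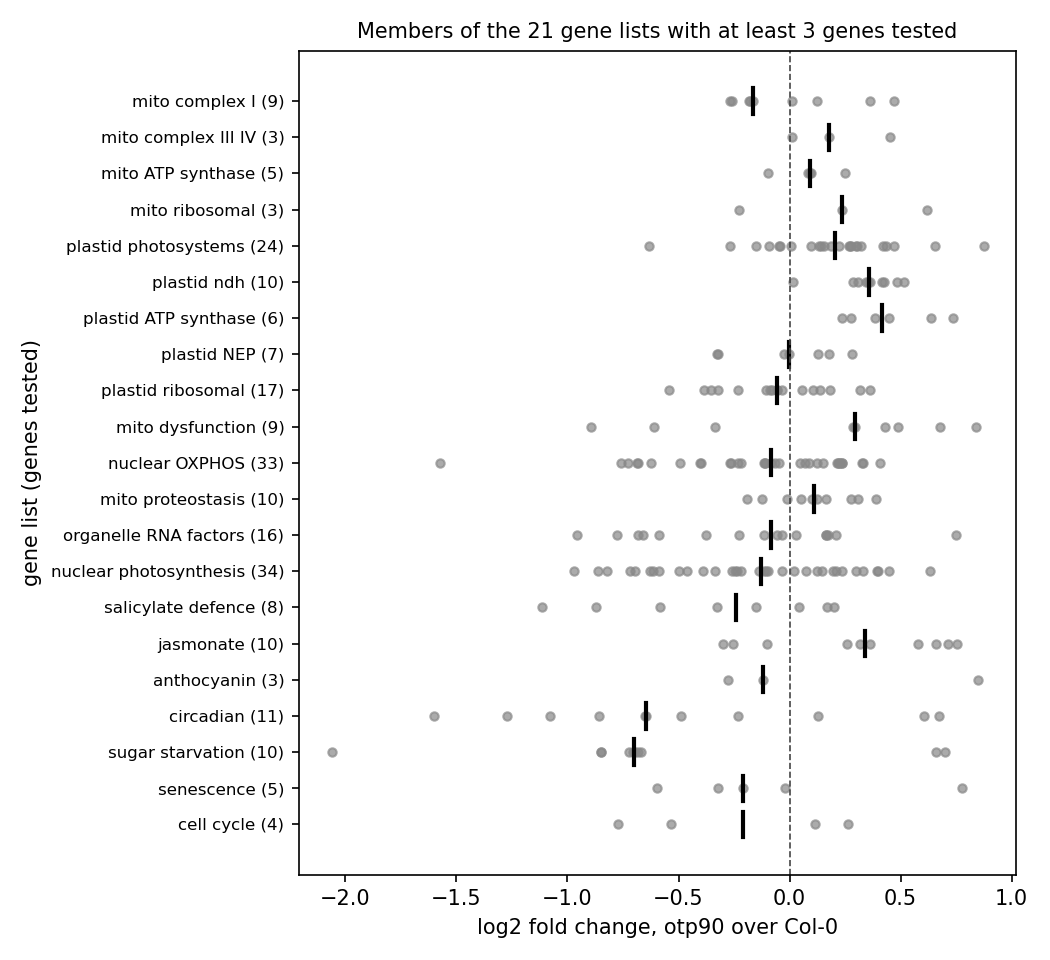
Log2 fold change of otp90 over Col-0 for each tested member of the 21 gene lists that camera could test. Grey points are genes and black bars list medians, which run from -0.70 in the sugar starvation list to 0.42 in the plastid ATP synthase list.

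By camera with the preset correlation, 0 of the 21 lists passed at an adjusted p under 0.05, and the smallest adjusted p was 0.281. At an unadjusted p under 0.05 there were the plastid NDH (0.0205) and ATP synthase (0.0267) lists. With an estimated correlation the adjusted p of camera was 0.982 in each list. With 2 libraries per genotype that estimate has little to rest on, so those values cannot decide. No list member was called over all genes tested, and 0 were called adjusted over the list alone. Leaving out 1 library gave 4 lists without otp90 replicate 1, 4 without otp90 replicate 2, 2 without Col-0 replicate 1 and 3 without Col-0 replicate 2. In each of those fits 1 genotype has only 1 replicate number, so genotype and number cannot be told apart. Between libraries of the same number, the medians of 10 of the 21 lists had opposite signs in numbers 1 and 2. These were the lists of mitochondrial ATP synthase, plastid genes read by the nuclear-encoded polymerase, plastid ribosomal, respiratory chain, nuclear photosynthesis, jasmonate, flavonoid, circadian, senescence and cell cycle genes.

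The libraries differed more by replicate number than by genotype, a comparison made after this was seen. With genotype as a term, edgeR called 96 genes between numbers, 92 lower and 4 higher in number 2. ASN1 (AT3G47340), the dark-induced asparagine synthetase gene, was at 101 and 178 CPM in otp90 and Col-0 of number 1, and at 0.569 and 1.09 CPM in number 2. The chlorophyll-binding protein gene LHCB1.1, which has near-identical copies, fell by 6.65 on the log2 scale in number 2 (adjusted p = 0.000126). The trehalose phosphate synthase family gene TPS11 (-5.72), LHCB2.2 (-4.14), the dark-inducible gene DIN10 (-3.45) and the clock gene PRR7 (-3.81) fell too, while the flavonol synthase gene FLS1 rose by 2.93 (adjusted p = 0.0219). DESeq2 with the genotype term called 99. Without that term edgeR called 113 genes and DESeq2 176, and without the low-count filter edgeR with the term called 214. Calls without the genotype term were 511 without otp90 replicate 1, 178 without otp90 replicate 2, 207 without Col-0 replicate 1 and 209 without Col-0 replicate 2.

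**Figure D3:**
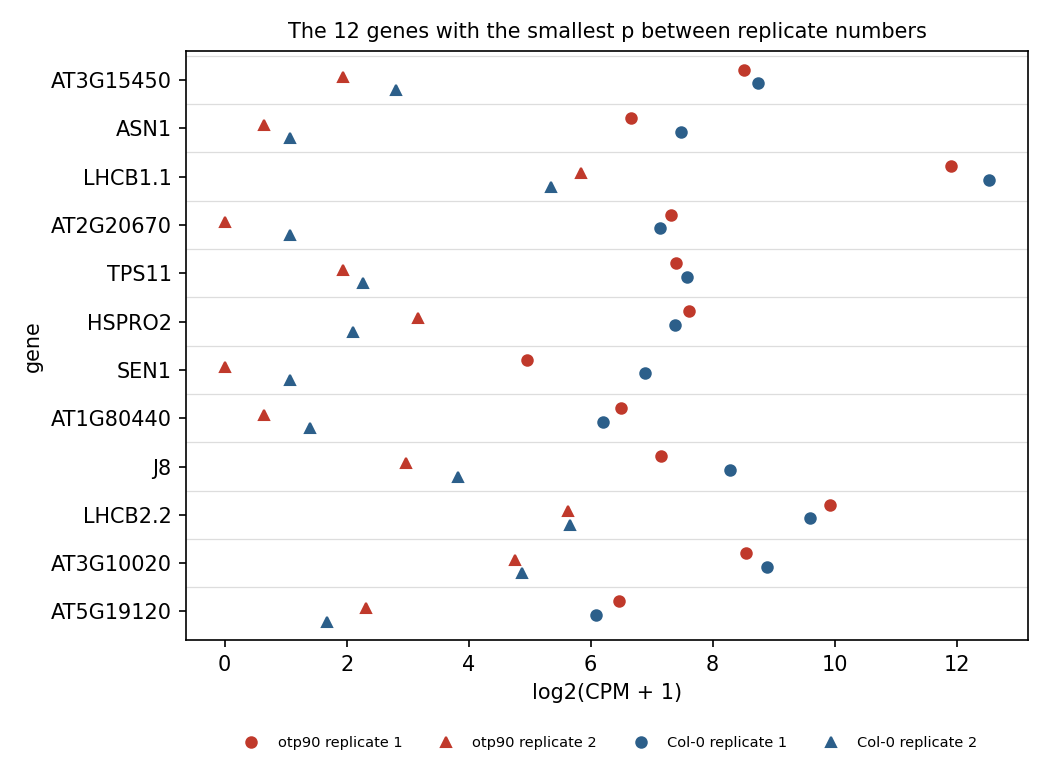
Levels of the 12 genes with the smallest p between replicate numbers in each library, as log2(CPM + 1) on the horizontal axis. Circles are replicate 1 and triangles replicate 2, red for otp90 and blue for Col-0, and in each gene both number 1 libraries lie above both number 2 libraries, as in LHCB1.1 (3845 and 5928 against 56.3 and 39.8 CPM).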

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

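The older and robust quasi-likelihood fits, the restriction to protein-coding nuclear genes, each library left out with rRNA genes kept and all alternatives of the comparison of replicate numbers were chosen after seeing the data. The count of 0 called genes, of 0 mitochondrial and of 0 plastid genes held under every scaling, filter and test run with all 4 libraries (the restriction to nuclear genes tests no organelle gene and gives only the first), with 96 (DESeq2) to 728 (no low-count filter) genes at an unadjusted p under 0.05. The smallest adjusted p in these was 0.176, by the likelihood ratio test. With 1 library left out, where the lone library is assumed to vary like the others, called genes ranged from 0 to 33, higher genes from 0 to 30, lower genes from 0 to 22, and lists from 2 to 4. Mitochondrial and plastid calls stayed at 0. Without the low-count filter 1 list passed. The cause was not tested.

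With the replicate block, 0 genes were called and 257 reached an unadjusted p under 0.05, and the smallest adjusted p of a list was 0.0531, for sugar starvation. Deviations of same-numbered libraries from their group means correlated at 0.22 across genes, and with 2 pairs and no label for a shared batch the numbers were not used as pairs. With the replicate block HSP90.1 was at 0.45 and CHS at 0.32, against -0.10 and -0.28 without, and with limma voom at 0.99 and 0.39. With limma voom LHCB1.1 was at 0.053, against -0.61. Some genes that changed sign with 1 library left out kept their sign under the alternatives with all 4 libraries, but moved. Examples are F3H from 0.85 to 2.17, ASN1 from -0.85 to -1.81, SEN1 from -2.06 to -3.37 and PRR5 from -1.27 to -0.77.

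The mitochondrial share differed by 0.273 percentage points with rRNA genes kept, which adds rrn26, by -0.061 to 0.098 with 1 library left out, and with both by -1.09 (without otp90 replicate 1), 1.63 (without otp90 replicate 2), 0.722 (without Col-0 replicate 1) and -0.176 (without Col-0 replicate 2). A share over protein-coding genes alone was not run, because the annotation used does not pair organelle locus tags with a gene type. Genes differing between replicate numbers were 96 by edgeR and 99 by DESeq2 with genotype as a term, and 214 by edgeR without the low-count filter. Without the genotype term they were 113 by edgeR, 176 by DESeq2, and 178 to 511 by edgeR with 1 library left out, where that term leaves no residual degrees of freedom.

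Of the 62 genes named here for the genotypes, 24 changed sign when 1 library was left out, and 28 of the other 38 moved by over 1.5 times. For those that changed sign the lowest and highest values were -0.14 and 1.22 for nad4, -0.066 and 0.87 for cox3, -0.12 and 0.52 for cox2, -0.10 and 0.75 for atp9, -0.40 and 0.50 for atp4, -0.63 and 0.25 for rpl16, -0.75 and 0.036 for ycf1, -0.72 and 0.10 for rpl14, -1.41 and 0.025 for NDB2, -0.12 and 0.79 for FTSH4, -0.012 and 0.75 for mtHSC70-2, -1.66 and 0.0032 for PSAF, -0.27 and 0.43 for HSP101, -0.99 and 2.67 for HSP90.1, -0.073 and 3.85 for F3H, -1.16 and 2.29 for CHS, -2.05 and 0.72 for PRR5, -1.51 and 0.47 for FKF1, -9.91 and 3.64 for SEN1, -0.50 and 3.80 for SAG13, -3.03 and 2.51 for WRKY53, -5.71 and 5.62 for LHCB1.1, -7.14 and 5.42 for ASN1, and -1.56 and 0.052 for KNOLLE. Of those that moved and kept their sign, rpl2, psaI and psbI are given in the report, AT1G17350 (1 count in otp90) is given there as a ratio, and the others had 1.60 and 3.11 for AT4G02540, 1.75 and 3.38 for CYP705A18, 0.075 and 1.08 for nad1, 0.047 and 0.72 for ccmFN2, 0.12 and 1.02 for mttB, 0.24 and 0.73 for ndhG, 0.25 and 0.89 for ndhJ, 0.29 and 1.11 for atpH, 0.26 and 0.97 for atpI, -0.56 and -0.080 for rpoA, -1.01 and -0.16 for rps16, 0.33 and 1.15 for AOX1A, -1.01 and -0.45 for AT5G08690, -1.02 and -0.45 for MORF9, 0.44 and 1.18 for SIG3, 0.091 and 1.57 for GAPB, -1.64 and -0.20 for PAD4, -0.81 and -0.27 for EDS1, 0.25 and 1.05 for AOS, 0.12 and 1.96 for LOX2, -1.05 and -0.12 for MCCB, -1.68 and -0.25 for CDKB2;2, 0.066 and 1.93 for PYK10, and 1.43 and 4.30 for MIR398c. Camera's p for nuclear photosynthesis ranged from 0.000532 to 0.35.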

Other observations

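The tests of a shared batch, of the variance that length and GC trends explain and of a single library behind MIR398c and CSD2 were chosen only after the result was seen, as were the comparison of replicate numbers and the counts of genes at 0. MIR398c, CSD2 and the copper list lie outside the rule for named genes and were chosen after the values of that pair were seen. Pentatricopeptide repeat genes, the family to which many organelle transcript processing factors belong, had a median log2 fold change of 0.15, with 57 of 99 tested positive. By edgeR 0 were called and 1 reached an unadjusted p under 0.05, and this group was chosen after seeing the data. The group held 309 gene models. CRR2 is annotated as a tetratricopeptide repeat-like protein, so annotated products can miss members of the family. Genes at 0 counts in both otp90 libraries and with at least 5 in both Col-0 libraries numbered 5: PIL2, a PIF3-like transcription factor gene (13 and 7 counts in Col-0), AT2G18670 (10 and 7), AT3G24760 (10 and 5), AT3G50120 (7 and 11) and AT1G31935 (8 and 11). None is annotated as a pentatricopeptide repeat gene, and the reverse direction gave 1 gene, while splits by replicate number gave 13 and 11 and the crossed splits 8 and 4.

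Between replicate numbers, 3 sugar starvation genes (ASN1, SEN1 and DIN10), 9 nuclear photosynthesis genes (LHCB1.1, LHCB1.2, LHCB1.4, LHCB1.5, LHCB2.1, LHCB2.2, LHCB2.3, LHCB3 and LHCA4) and the clock genes PRR7 and GI were lower in number 2 at an adjusted p under 0.05 by edgeR. FLS1 was higher in number 2. In the sugar starvation list 9 of 10 genes were lower in number 2 in both genotypes, with a median of -1.88, and in the flavonoid list 3 of 3 were higher, with a median of 2.45. With the preset correlation camera passed 12 of 21 lists between numbers, and with an estimated one 0 of 21. The estimated correlation has little to rest on with 4 libraries and terms for genotype and number, so that 0 cannot decide. The 12 included sugar starvation (adjusted p = 6.24e-10), flavonoids (2.82e-05), nuclear photosynthesis (8.62e-07), senescence (0.000251, median -2.71), plastid photosystems (0.000776), mitochondrial dysfunction (0.000863) and salicylic acid (0.0078).

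The first pattern weighed is that the 4 libraries separated by replicate number (47.3% of the variance between libraries) more than by genotype (22.4%), the crossed split taking 30.3%. Counting noise at low depth was argued against, because among 935 genes with a mean of at least 200 counts the genotype share was still the smallest, at 13.951%. Removing trends with gene length and GC content left the number share at 47.669%, from 47.678%, and moved too little to test them, but such trends explained only 1.14% (95% bootstrap interval over genes 0.771 to 1.498) of the variance of the number difference across 11511 genes, which argues against them as the main cause. A candidate explanation is that plants of 1 replicate number shared a growth or harvest batch, with light or carbon supply that differed between batches. The design cannot tell it apart from others. For the 4 lists that follow light or carbon, the smallest adjusted p of camera was 0.5995 with an estimated correlation. That test cannot decide, because 4 libraries with terms for genotype and number leave too little to estimate a correlation. The labels name no batch, and no biological explanation was tested.

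The second pattern is a higher MIR398c and a lower CSD2 in otp90. MIR398c, the precursor of a microRNA that acts against copper superoxide dismutase transcripts, had a log2 fold change of 2.64 (SE 0.86). Its target CSD2 had one of -1.53 (SE 0.52). With all 4 libraries edgeR called neither (adjusted p = 0.9998 each). MIR398c was called without otp90 replicate 1 (log2 fold change 3.30) and without Col-0 replicate 1 (4.30). Each of those fits leaves 1 genotype with number 2 alone, so genotype and number cannot be told apart. MIR398c had 17 counts in otp90 and 21 in Col-0 in number 1 (14.1 and 8.62 CPM). In number 2 it had 91 and 3 (51.8 and 1.64 CPM). A copper-deficiency response may contribute, as a hypothesis. The other 8 measured genes of a copper list had a mean log2 fold change, signed by expected direction, of 0.34, with 5 of 8 in that direction. Its 95% interval of -0.10 to 0.77 was taken over these genes and does not measure the spread between libraries. CSD1 (log2 fold change -0.63), another copper superoxide dismutase gene among them, may follow MIR398c itself, as other members may. Such members are not separate evidence of a copper response. Camera gave p = 0.0172 for the 8 genes with the preset correlation and 0.133 with an estimated one, so the copper hypothesis stays open. A single library behind the pattern stays open too, since without otp90 replicate 2 MIR398c kept 0.542 of its log2 fold change, at 1.43 with an SE of 1.04, although it kept at least 0.744 in the other settings and CSD2 kept 0.687 to 1.42 in all 4. An effect of the genotype itself stays open, since the test between genotypes called neither gene with all 4 libraries and nothing else in the design tests it.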
